A study of Drosophila melanogaster with 4 samples.

How the data were processed

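Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers DNA fragments bound by a protein and maps them to the genome. The protein here was CG1233 of Drosophila melanogaster, carried as a fusion with green fluorescent protein (GFP) at its C terminus in a transgenic line. Chromatin came from whole embryos of both sexes collected 0 to 24 h after laying and was sonicated to fragments of 200 to 800 bp, per the labels. The 4 biological replicates formed 1 group, so no groups were compared. The labels disagree on what the libraries are: the description of each sample calls it the input control, while the antibody field names CG1233 and the assay is given as transcription factor ChIP-seq. The peak lists were read as ChIP calls, and the disagreement could not be settled from the lists.

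The deposited peak lists are on the dm6 build, per the text files deposited with the samples. Each replicate had a list called from its own alignment against 1 control alignment set that all 4 replicates shared. A pooled list came from the 4 alignments together, against the same control. Each of these 5 lists held 30000 calls and included weak background calls. An irreproducible discovery rate (IDR) step then gave an optimal list of 5211 peaks. The aligner, peak caller and their versions were not given in the sources used here. Tested on the files, the 5211 optimal peaks were the 5211 strongest pooled calls, with identical positions and signals. They covered 5201 intervals, of which 10 carried an additional summit, and counts are by summit. The deposited signal column is the caller's own coverage score for each call, on a scale that differs between lists. It was used only to rank or filter calls within 1 list. The deposited q-value column holds −log10 q, and the p-value column was filled with -1 and not used. The deposited lists give no read counts, so the sequencing depth of each replicate is unknown, and no value could be weighted by depth.

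Positions were read as 1-based dm6 coordinates, and no call ended beyond the end of its arm in the reference. Genes came from the Ensembl 115 annotation of the same assembly, without transposable elements, on arms X, 2L, 2R, 3L, 3R and 4. A summit within 500 bp of any annotated transcription start site (TSS) was a promoter summit. Other summits were placed in the 5′ UTR, coding sequence (CDS), 3′ UTR, other exons, introns or intergenic sequence, in that order. A gene had a promoter peak when an optimal summit lay within 500 bp of one of its TSSs, and 1 peak could serve several genes. An optimal peak counted as held by a replicate when 1 of that replicate's 5211 strongest calls had its summit inside it. The background for positions and arms was the 23780 pooled calls outside the optimal list, after 1009 that overlapped an optimal peak were set aside. Since the optimal list is a cut in the pooled list by rank, this comparison sets strong against weak calls.

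Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family (7 position classes, 6 arms, 32 gene lists, 6 biotypes and 16 motifs). Arms were also compared with arm length by an exact binomial test. Shares carry 95% exact Clopper-Pearson intervals. Where a count was 0, the upper limit is 3 counts of the total. Intervals and limits cover counting error only, and neighbouring peaks or genes are not independent. Values per replicate are given as mean ± SD over the 4 replicates. Motif words were searched on both strands within 50 bp of each summit and compared with windows centred 500 bp away on the lower-coordinate side, by an exact McNemar test. Words of 7 bases were chosen on arms 2L, 3L and 4 and tested on arms X, 2R and 3R. Ranks were compared by a two-sided permutation test with 100000 draws. Random placement kept the arm and width of each peak and was repeated 100 times. Rank correlations are across peaks, which are not independent replicates, and carry no p-value.

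The gene lists, motifs, tests and most alternatives were chosen before the data were examined. Of 284 symbols listed singly, 277 matched the annotation, 2 matched through a RefSeq synonym and 5 (Dl, dys, nos, phm and Kipferl) did not match and were left out. Matching by synonym was added after the counts had been seen. A further 11 lists were gene families defined by their symbols. Genes were named by a rule: CG1233, the 20 protein-coding genes with the strongest promoter peaks held by all 4 replicates (all genes of a shared peak are named), up to 4 genes with the strongest peaks of each list, and the genes in counts of 5 or fewer. Not every gene the rule names is reported here. The alternatives were promoter windows of 200 and 1000 bp, the 5′-most TSS, the nearest TSS within 5000 bp, other backgrounds, the strongest 2605 optimal peaks, only peaks held by all 4 replicates, each replicate left out in turn, motif windows of 25 and 100 bp, and words of 6 and 8 bases. Added after seeing the data were gene lists restricted to peaks held by the 3 other replicates, positions restricted to peaks held by all 4, motifs at promoter and other peaks separately, motifs read backwards, and other settings for the named genes and for CG1233.

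The calculations were tested on simulated data before use. In 5211 simulated peaks with 80% of 1 gene list planted, 81.0% of that list was recovered, with 0 of the 31 other lists called. All 5 planted words were recovered, and a planted replicate share of 70% came back as 70.5%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.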

Results

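Binding of CG1233-GFP was mapped by ChIP-seq in whole Drosophila embryos aged 0 to 24 h, in 4 biological replicates of 1 transgenic line. The sample descriptions call these libraries input controls, whereas their antibody field names CG1233, and all values below rest on reading them as ChIP. The authors' optimal list held 5211 peaks with a median width of 424 bp. Each replicate list held 30000 calls, of which 6697, 4575, 10424 and 5400 had a −log10 q above 2 in replicates 1 to 4. The lists give no read counts, so the depth of each replicate is unknown.

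Of the 5211 optimal peaks, 2513 (48.2%) were among the 5211 strongest calls of all 4 replicates, and 17 were in none. Single replicates held 78.6% ± 7.97 of the peaks (SD, n = 4), with 74.3% in replicate 1, 86.8% in replicate 2, 69.7% in replicate 3 and 83.7% in replicate 4. The optimal list was called from the same 4 alignments against the same control, so agreement is built in to an unknown degree. Peaks placed at random were held at 1.41% on average over 100 placements, a lenient comparison that leaves this out of account. Spearman's rho between replicate ranks, across peaks, averaged 0.655 ± 0.118 (SD over 6 pairs). It was highest between replicates 2 and 4 (0.843) and between replicates 1 and 3 (0.721), and lowest between replicates 3 and 4 (0.513). No label separates these pairs.

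Promoters, taken as 500 bp to either side of a TSS, held the largest share of the optimal peaks, a ranking that depends on this width. Of 5211 summits, 2424 (46.5%, 95% interval 45.2 to 47.9%) lay within 500 bp of a TSS, against 24.7% of the weaker pooled candidates (odds ratio 2.65, Fisher's exact test, adjusted p = 1.27e-202). The replicates' own strongest calls gave 48.2% ± 3.22 (SD, n = 4). Introns held 36.9% of optimal and 44.9% of weaker calls (exact adjusted p = 8.85e-26), and intergenic sequence 13.6% and 22.3% (adjusted p = 8.30e-48). Coding sequence was nearly free of summits, with 11 peaks (0.211%) against 3.58% of weaker calls (exact adjusted p = 8.13e-58) and 13.5% of random positions. The 3′ UTR share was also lower (1.07% against 2.35%, exact adjusted p = 7.87e-10), as was that of the 5′ UTR (0.652% against 1.03%, adjusted p = 0.0113). The 5′ UTR call, with an odds ratio of 0.631, ended against random positions (0.828, exact adjusted p = 0.332) and with only peaks held by all 4 replicates (0.654, adjusted p = 0.107). Other exons did not pass the test (1.02% against 1.11%, exact adjusted p = 0.607).

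**Figure D1:**
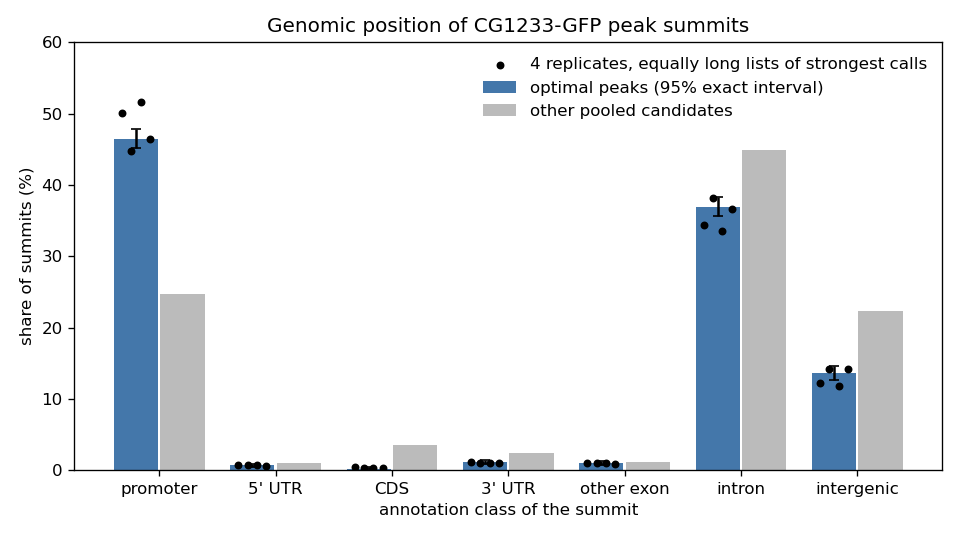
Share of peak summits (y axis, %) in each annotation class (x axis). Blue bars are the 5211 optimal peaks with 95% exact intervals, grey bars the 23780 weaker pooled candidates, and black points the strongest calls of each of the 4 replicates. Promoters held 46.5% of optimal and 24.7% of weaker summits.

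The strongest promoter peaks lay at genes of varied function, several of them at head-to-head pairs. The 2 strongest held by all 4 replicates were at CG14100 (FBgn0036889), with a peak on 3L from 19590423 to 19590821, summit 91 bp upstream of the TSS (position -91), and at Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, with a peak on X from 2703683 to 2704084. They ranked 5 and 6 in the optimal list, and between ranks 3 and 13 in every replicate. Next came CG14434 on X (rank 7) and mRpL41, a mitochondrial ribosomal protein gene on 2R (rank 9, peak from 15217554 to 15217949). The wing vein gene px followed at rank 11, and the divergent pair Art3 and mRpS10, sharing a peak on 3R from 15229355 to 15229717, at rank 13. The Polycomb group gene ph-p on X had the peak of rank 14 (2137163 to 2137571), and CG1888 that of rank 16. The shared peaks of mRpS23 and CenG1A (rank 18), Tcs5 and CHMP2B (rank 22), Chro and Ssl1 (rank 25), eIF4EHP and CG18428 (rank 28) and Pdrg1 and Pal1 (rank 29) cannot be assigned to 1 gene of each pair. CG18549 (rank 21) and PNPase, a mitochondrial exoribonuclease gene (rank 27), complete the set.

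The 4 strongest peaks of the list were not at promoters but inside CG14434 (FBgn0029915, X from 6851909 to 6867194, minus strand), a locus described here after its values were seen. Ranks 1 and 2 had summits at 6861721 and 6862824, in an exon of the overlapping long noncoding RNA gene lncRNA:CR45531. Ranks 3 and 4 had summits at 6853480 and 6866196, in introns, and rank 7 was at the CG14434 promoter (summit 6867283). Across the replicates these 5 peaks ranked between 1 and 9. The span of 13803 bp between the outer summits, widened by 1 kb on each side, held 12 optimal summits.

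**Figure D2:**
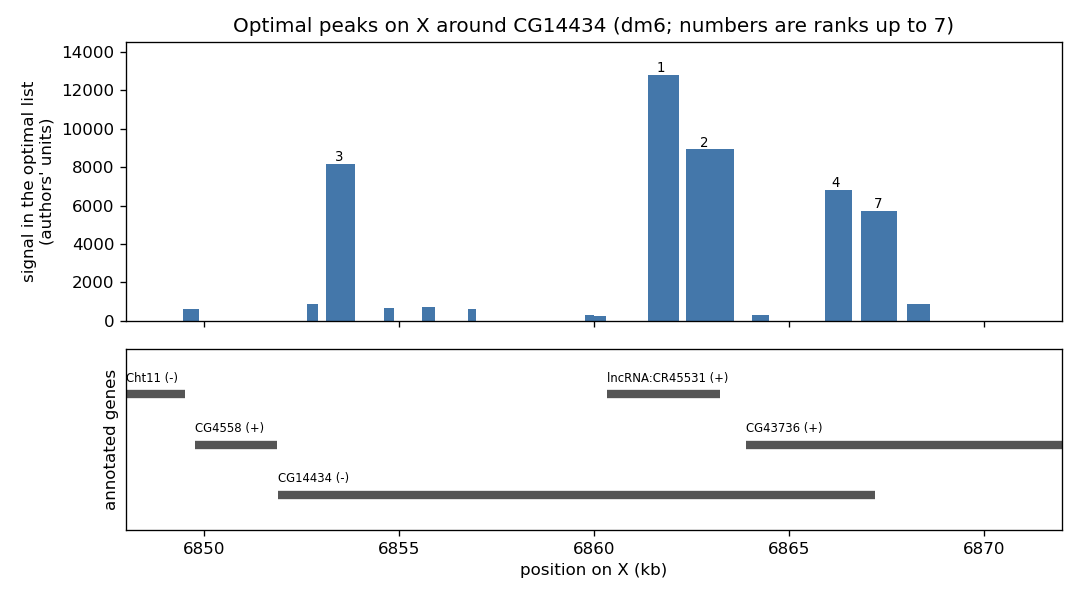
Upper panel, signal of each optimal peak (y axis, the authors' units) against position on X in kb (x axis, dm6), with bar width equal to peak width and ranks up to 7 written above. Lower panel, annotated genes with strand. Ranks 1, 2, 3, 4 and 7 all lie in or at the promoter of CG14434.

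Genes of the cytosolic ribosome carried promoter peaks far more often than other genes. Of 86 cytosolic ribosomal protein genes, 72 (83.7%, 95% interval 74.2 to 90.8%) had one, against 2779 of all 13945 protein-coding genes (19.9%; odds ratio 21.2, Fisher's exact test, adjusted p = 1.26e-35). The replicates' own strongest calls marked 69.5 ± 1.29 of them (SD, n = 4). The large subunit had 44 of 48 genes with a peak and the small subunit 28 of 38. RpS27 (rank 52), RpL7 (rank 85) and RpL14 (rank 168) were among those with the strongest. Their summits lay close to the TSS, with a median of -18 bp and quartiles of -36 and 2.25 bp. Genes for insulator and chromatin architecture proteins followed, with 11 of 16 (68.8%, odds ratio 8.87, exact adjusted p = 1.99e-04). Among them were Chro, Cp190, which encodes an insulator cofactor (rank 93), M1BP (rank 228) and Dref (rank 347), the last 2 encoding promoter-binding factors. Of 73 mitochondrial ribosomal protein genes, 27 (37.0%) had a peak (odds ratio 2.37, exact adjusted p = 0.00334), led by mRpL41, mRpS10, mRpS23 and mRpL23 (rank 66). With genes assigned by nearest TSS, the odds ratio was 0.653 for the mitochondrial list (exact adjusted p = 0.445) and 2.87 for the insulator list (adjusted p = 0.187), and both calls ended. The mitochondrial call also ended in the strongest 2605 peaks (exact adjusted p = 0.111), with peaks held by all 4 replicates (adjusted p = 0.121), and without replicate 1 (adjusted p = 0.151) or replicate 4 (adjusted p = 0.274). Among genes with any pooled candidate call at the promoter, the cytosolic list alone kept its call (exact adjusted p = 1.81e-16), and that of insulator genes had an adjusted p of 0.0691.

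Chemoreceptor and cuticle genes had fewer promoter peaks than other genes, and histone genes had none, in a repeated cluster without any call. None of 111 replication-dependent histone genes had one (0%, which allows up to 2.70%; exact adjusted p = 2.85e-10). The histone cluster on 2L, from 21416953 to 21541681, also had 0 calls in every list, including the weak candidates. Its near-identical copies may yield no calls at all. The histone test and its upper limit therefore cannot tell absent binding from absent calls, and no depletion is concluded. Of 179 odorant, gustatory and ionotropic receptor genes 1, Ir60e, had a peak (0.559%, exact adjusted p = 4.04e-15). Of 93 cuticle protein genes 1, Cpr65Av, had one (1.08%, exact adjusted p = 4.30e-07). With genes lacking any candidate call left out, these receptor and cuticle calls ended (exact adjusted p = 0.0691 and 0.0826).

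**Figure D3:**
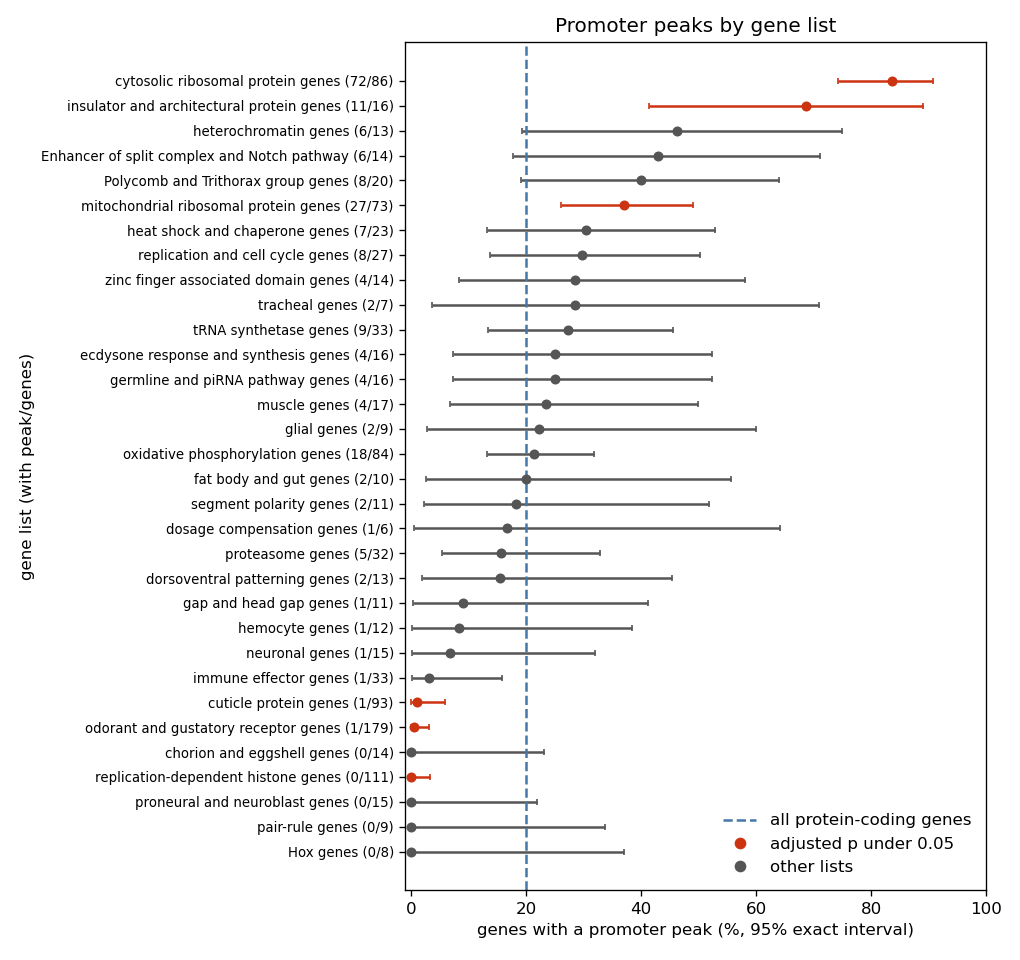
Share of genes with a promoter peak (x axis, %, with 95% exact intervals) in each of 32 gene lists (y axis, genes with a peak and genes in the list). Red points passed an adjusted p of 0.05 in Fisher's exact test, and the dashed line is the 19.9% of all protein-coding genes. Cytosolic ribosomal protein genes stand highest at 83.7%.

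The other lists did not pass the test after adjustment, among them the embryonic patterning genes. None of 8 Hox genes, 9 pair-rule genes, 15 proneural and neuroblast genes or 14 chorion and eggshell genes had a promoter peak, which allows up to 37.5%, 33.3%, 20% and 21.4%. Assigned by nearest TSS within 5000 bp, the odds ratio turned from 0.236 to 3.69 for Hox, from 0.211 to 1.05 for pair-rule and from 0.129 to 1.85 for proneural genes, none past the threshold (exact adjusted p = 0.202, 1 and 0.477). Single genes had one among the 11 gap and head gap genes (cnc), 15 neuronal genes (elav, rank 106), 12 hemocyte genes (ush), 6 dosage compensation genes (Clamp) and 33 immune effector genes (PGRP-LB). The immune effector list had an exact adjusted p of 0.0633 and passed with a promoter window of 1000 bp (adjusted p = 0.0164) or with the 5′-most TSS alone (adjusted p = 0.0110). Peaks lay at 2 genes each of the segment polarity (nkd and ci, of 11), dorsoventral (cact and rho, of 13), glial (moody and pnt, of 9), fat body and gut (fkh and GATAe, of 10) and tracheal lists (trh, rank 72, and bnl, of 7). The Notch pathway and Enhancer of split list had 6 of 14 (exact adjusted p = 0.138), led by E(spl)m3-HLH (rank 250), numb (rank 266), E(spl)m7-HLH (rank 510) and neur (rank 641). Its odds ratio of 3.02 became 6.85 with only peaks held by all 4 replicates (exact adjusted p = 0.00742), 0.482 with a window of 200 bp (adjusted p = 0.872) and 1.40 among genes with a candidate call (adjusted p = 0.939). With each replicate left out in turn, using peaks held by the others, it was 5.56 to 6.48 (exact adjusted p from 0.00965 to 0.0167). Polycomb and Trithorax group genes had 8 of 20 (exact adjusted p = 0.138), with ph-p, brm (rank 79), E(z) (rank 184) and Trl the strongest. Heterochromatin genes had 6 of 13 (exact adjusted p = 0.118), with row, HP4 and HP5 the strongest. Their odds ratio of 3.45 fell to 0.758 with only peaks held by all 4 replicates, and to 0.717, 0.615 and 0.683 without replicates 2, 3 and 4 (exact adjusted p = 1 in each). It was 2.41 without replicate 1 (exact adjusted p = 0.489) and 3.99 with the 5′-most TSS (adjusted p = 0.0675). Among genes with a candidate call it was 4.21 (exact adjusted p = 0.319).

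Among general cellular functions, oxidative phosphorylation genes had 18 of 84, close to the share of all genes (21.4%, exact adjusted p = 0.835), with ND-ASHI, ND-MWFE, ND-42 and ND-SGDH the strongest. Proteasome genes had 5 of 32 (exact adjusted p = 0.835), with Rpn5, Prosalpha4, Rpn3 and Rpn11 the strongest. tRNA synthetase genes had 9 of 33 (SerRS, GluProRS, ThrRS and AspRS; adjusted p = 0.558), and replication and cell cycle genes 8 of 27 (CycE, RnrS, Dp and Mcm2; adjusted p = 0.482). Heat shock and chaperone genes had 7 of 23 (Hsp83, rank 110, Hsp27, Hsc70-5 and stv; exact adjusted p = 0.482). Muscle genes had 4 of 17 (tin, sls, Tm1 and Act87E), germline and piRNA genes 4 of 16 (bgcn, gcl, piwi and vas), and ecdysone genes 4 of 16 (Eip75B, usp, ftz-f1 and Hr39). Zinc finger associated domain genes had 4 of 14 (M1BP, Zaf1, trem and hang; exact adjusted p = 0.787).

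Noncoding genes of 5 biotypes had promoter peaks less often than protein-coding genes, and small nuclear RNA (snRNA) genes did not pass the test. Of 3261 ncRNA genes 236 had one (7.24%, exact adjusted p = 1.45e-76), of 290 tRNA genes 19 (6.55%, adjusted p = 6.27e-10) and of 269 snoRNA genes 25 (9.29%, adjusted p = 4.91e-06). With a window of 1000 bp, the snoRNA odds ratio of 0.412 became 1.16 (exact adjusted p = 0.370). Pseudogenes had 9 of 268 (3.36%, exact adjusted p = 7.76e-15) and rRNA genes, present in repeated copies, 0 of 99 (which allows up to 3.03%; adjusted p = 6.35e-10). snRNA genes had 7 of 32 (21.9%, adjusted p = 0.824). Head-to-head promoters stood out among protein-coding genes. Of 4914 genes with an opposite TSS within 1000 bp upstream, 1669 (33.96%, 95% interval 32.6 to 35.3%) had a peak, against 1110 of 9031 others (12.3%; odds ratio 3.67, Fisher's exact p = 1.97e-197). A single peak between paired genes counts for both, which raises the first share.

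Most promoter summits lay upstream of the nearest TSS. The median of 2424 was at -100.5 bp, with quartiles at -200 and -12 bp, and 1877 (77.4%, 95% interval 75.7 to 79.1%) were upstream. A summit between head-to-head TSSs counts as upstream whichever is nearer, and such pairs were not separated here. Weaker candidates had a median of -21 bp and 55.0% upstream. The medians of the replicates' own calls were -51, -113, -47 and -124 bp (mean -83.75 ± 40.4 SD, n = 4), with replicates 1 and 3 close to each other, and 2 and 4. Promoter peaks ranked above other peaks by 5.94 percentile points (53.2 against 47.2, permutation p = 1e-05, the smallest the draws can give). The difference was 2.93 points with a promoter window of 200 bp (permutation p = 6.40e-04) and 3.66 with peaks ranked by q-value (permutation p = 1e-05). In the replicates' own lists this difference was 2.33, 8.89, 0.498 and 9.01 points (mean 5.18 ± 4.41 SD, n = 4), a spread close to the difference itself, and the same pairs lay together. No label separates them.

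**Figure D4:**
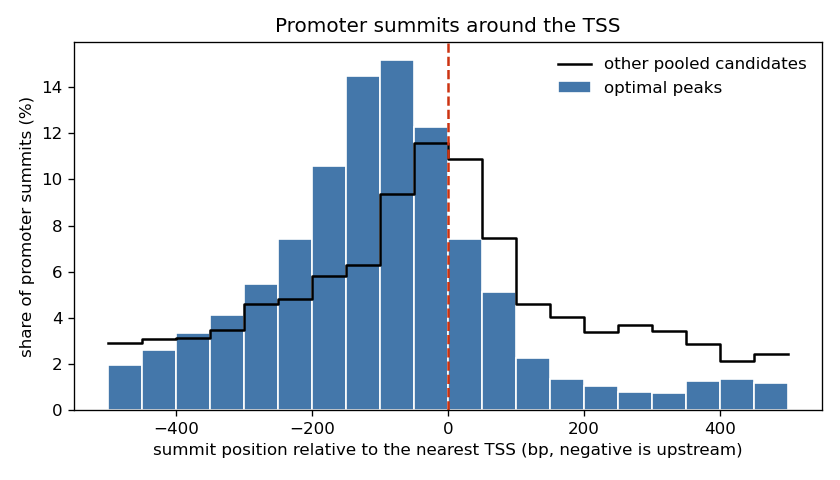
Share of promoter summits (y axis, %) in 50 bp bins of distance to the nearest TSS (x axis, bp, negative is upstream). Blue bars are the optimal peaks and the black line the weaker pooled candidates. The optimal summits have their median at -100.5 bp and the weaker ones at -21 bp.

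Of 16 motifs, 6 were more frequent at the summits than 500 bp away and 5 less frequent. The flanks were not matched for base composition, with a GC content of 35.1% at the summits and 43.2% in these flanks. AT-rich motifs could be higher, and GC-richer ones lower, for this reason alone, which was not tested. The DNA replication-related element TATCGATA, the site of Dref, was at 68 summits (1.305%) against 0.365% of flanks (exact adjusted p = 3.78e-07). Ohler motif 1 (GGTCACACT), the site of M1BP, was at 0.614% against 0.115% (exact adjusted p = 6.49e-05), and CATCNCTA at 1.305% against 0.595% (adjusted p = 5.84e-04). The TATA box STATAAA (6.29% against 3.93%, exact adjusted p = 3.78e-07), the Su(Hw) core (0.672% against 0.211%, adjusted p = 0.00107) and ATATATAT (2.63% against 1.42%, adjusted p = 4.54e-05) were also higher. At non-promoter peaks, the odds ratio of the DRE was 0.692 (exact adjusted p = 0.928), against 5.08 (adjusted p = 2.71e-08) at promoter peaks. That of the TATA box was 1.67 at non-promoter peaks and 1.60 at promoter peaks. Against weaker candidates, odds ratios fell from 3.65 to 1.87 for the DRE (exact adjusted p = 1.93e-04), from 5 to 1.76 for Ohler motif 1 (adjusted p = 0.0203) and from 2.17 to 1.41 for CATCNCTA (adjusted p = 0.0268). Fewer of these candidates are promoter summits (24.7% against 46.5% of optimal peaks), and the comparison was not matched for promoter share. The Su(Hw) call ended against weaker candidates (exact adjusted p = 0.177), those of Ohler motif 1 and CATCNCTA in the strongest 2605 peaks (adjusted p = 0.0872 and 0.231), and that of ATATATAT with a window of 25 bp (adjusted p = 0.05004). The consensus read backwards, a background chosen after seeing the data, is a different word at the same summits. It does not compare summits with flanks. Against it, the TATA box had an odds ratio of 0.492 (exact adjusted p = 1.29e-22), and ATATATAT did not pass (adjusted p = 0.155).

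The GAGA element was lower at the summits (1.23% against 2.86%, odds ratio 0.412, exact adjusted p = 3.51e-08; 0.645 against weaker candidates), as were CACACACA (2.00% against 3.74%, adjusted p = 3.78e-07) and the E-box CACGTG (0.729% against 1.38%, adjusted p = 0.00246). The CTCF core (1.73% against 2.48%, exact adjusted p = 0.0156) and the E-box CAGCTG (3.88% against 4.86%, adjusted p = 0.0228) were lower too. With a window of 25 bp the calls of CACGTG, CTCF and CAGCTG ended (exact adjusted p = 0.168, 0.377 and 0.542), as did that of CAGCTG with 100 bp (adjusted p = 0.509) and that of CACGTG in the strongest 2605 peaks (adjusted p = 0.152). The CTCF call also ended against the other flank (exact adjusted p = 0.120), in the strongest 2605 peaks (adjusted p = 0.05004) and against weaker candidates (adjusted p = 0.0615). Against the consensus read backwards, the odds ratios were 2.93 for CTCF (exact adjusted p = 1.36e-07), 5.96 for CAGCTG (adjusted p = 6.73e-29) and 1.10 for CACACACA (adjusted p = 1). These values compare different words at the summits, not summits with flanks, and do not reverse the lower shares. At promoter peaks alone, also chosen after seeing the data, CACACACA was the only one of these to keep its call (exact adjusted p = 6.69e-04). The Zelda site, the BEAF-32 core repeat, the Initiator, the Pho core and AAAAAAAA did not pass the test (exact adjusted p from 0.491 to 1). The Zelda site passed as lower with a window of 100 bp (odds ratio 0.638, exact adjusted p = 0.0284), and the Pho core against weaker candidates (odds ratio 0.819, adjusted p = 0.0203). Against its reversed form, again a different word at the same summits, the Pho core had 3.24 (exact adjusted p = 1.58e-17). All 10 words of 7 bases selected on 2103 peaks were AT-rich and were higher at the summits of the 3108 test peaks. TTTAAAA was at 11.1% of test summits against 3.86% of flanks (exact adjusted p = 3.38e-27) and AAATATT at 12.6% against 5.15% (adjusted p = 1.31e-24). GC content averaged 35.1% at the optimal summits and 43.2% at 500 bp on the lower-coordinate side, while weaker candidates had 41.6% and 41.3%. The difference between summit and flank was -3.57, -8.52, -4.03 and -9.54 points in the own calls of replicates 1 to 4, so that replicates 1 and 3, and 2 and 4, again lay together.

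**Figure D5:**
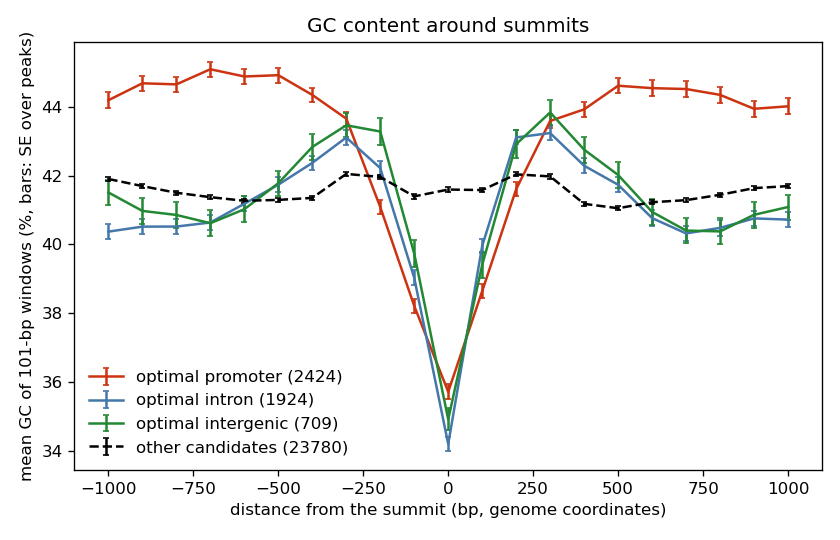
Mean GC content (y axis, %) in windows around peak summits by distance from the summit (x axis, bp), with bars of 1 standard error over peaks. Promoter, intron and intergenic optimal peaks all dip at the summit, to 35.7%, 34.2% and 34.9%, whereas the weaker candidates stay at 41.6%.

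Peaks were spread over all arms. X held 16.7% of the optimal peaks and 14.9% of weaker candidates (odds ratio 1.14, Fisher's exact test, adjusted p = 0.0114), and 3L 21.4% and 23.2% (odds ratio 0.900, adjusted p = 0.0142). Against arm length, X had an observed to expected ratio of 0.947 (exact adjusted p = 0.161) and 3L of 1.02 (adjusted p = 0.518), so neither direction held. Chromosome 4 had 19 peaks, 14.1 per Mb against 36.9 per Mb on X, and its ratio to arm length was 0.362 (exact adjusted p = 9.56e-07), while against weaker candidates it did not pass (adjusted p = 0.0878). Arms 2L, 2R and 3R did not pass the test against weaker candidates (exact adjusted p = 0.0604, 0.691 and 0.0604).

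The CG1233 gene itself (FBgn0035137, 3L from 361472 to 365681, plus strand) had no call in the optimal or pooled lists within 500 bp of the gene. Replicate 1 had a call with its summit at 361426, 46 bp upstream of the gene start (position -46, rank 3808), and another at 362174 (rank 9399). Replicate 3 had a call at 361374 (position -98, rank 2955). Replicates 2 and 4 had none. The tagged gene is also present as a transgene, which can itself give signal. The calls in replicates 1 and 3 therefore cannot be read as binding of CG1233 to its own gene.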

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

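All tests of this part were set by a fixed rule for values that stand apart from the other 3 replicates, and the checked measures were the values per replicate. Of 51 measures, 4 stood apart. The rule flags about 1 in 20 by chance for continuous, normally spread values, whereas many of these measures are small counts. Replicate 1 had 0.499% of its strongest calls in coding sequence, where replicates 2 to 4 had 0.230%, 0.250% and 0.269%. The other 3 are differences of 1 gene: replicate 4 marked 1 Hox gene where the others marked 0, replicate 3 marked 2 neuronal genes where the others marked 1, and replicate 2 marked 3 zinc finger associated domain genes where the others marked 4. With the other 3 values tied, the rule flags a difference of any size, so these flags carry no weight.

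Replicate 3 had 4 calls on the mitochondrial genome, which no comparison of the report used, and the other lists had 0. A count of 0 allows up to 3 by counting error alone, which does not allow for several summits in 1 interval. Their ranks in replicate 3 were 1, 2, 4 and 377. Of their summits, 3 lay in mt:CoI (positions 1852, 2052 and 2771) and 1 in mt:CoII (position 3548), which encode cytochrome c oxidase subunits. The 3 summits in mt:CoI shared 1 interval, from 1356 to 3088. No explanation was tested for these values.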

How the results depend on the processing

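Odds ratios for promoter position and head-to-head genes, the summit offset, rank agreement, and the cytosolic ribosomal protein call kept their direction and side of the threshold under every alternative run. Of the strongest 2605 peaks, 1369 were held by all replicates when each replicate list was also cut to its 2605 strongest calls. Over all optimal peaks, the count was 4587 with all calls of each list and 2637 to 3087 with a replicate left out. Arms past the threshold fell from 2 to 1 in the strongest 2605 peaks and to 1 against arm length, where the ratios of X and 3L were 0.947 and 1.02. Of 6 gene lists, 1 passed among genes with a pooled candidate call at the promoter, where the odds ratios were 1.90 for mitochondrial ribosomal protein, 5.15 for insulator, 0.0997 for receptor, 0.116 for cuticle and 1.40 for histone genes. The last compares no genes, since no histone gene had a candidate call. Assigned by nearest TSS, mitochondrial ribosomal protein genes had 0.653 and insulator genes 2.87, neither past the threshold. The mitochondrial list had 2.00 in the strongest 2605 peaks, 1.98 with peaks held by all 4 replicates, neither past the threshold, and 1.78 to 2.43 with a replicate left out, where its call ended without replicate 1 or 4. The leave-one-out lists use peaks held by the 3 other replicates. Motifs higher at summits numbered 2 at non-promoter peaks, where the DRE had 0.692. The consensus read backwards, chosen after seeing the data, is a different word at the same summits and does not test summit against flank. Against it, the odds ratio was 5.96 for CAGCTG, 0.492 for the TATA box, 2.93 for the CTCF core, 3.24 for the Pho core and 1.10 for CACACACA. The snoRNA odds ratio was 1.16 with a window of 1000 bp. Of the 92 genes named by the rule, 62 kept a peak within 200 bp of a TSS, 74 at the 5′-most TSS, and 63 with only peaks held by all 4 replicates. The cause of these changes was not tested. Depth is unknown, so what it limits could not be judged.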

Other observations

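The gene groups of this first paragraph were chosen after the data were seen, and p-values were adjusted over these groups alone. Translation initiation and elongation factor genes had a promoter peak in 18 of 51 cases (35.3%, odds ratio 2.20, Fisher's exact test, adjusted p = 0.0248), and the replicates' own calls marked 17.25 ± 0.957 of them (SD, n = 4). The unadjusted Fisher's exact p of this group was 0.0124. Among the 32 planned lists, immune effector genes with a similar unadjusted p (0.0138) did not pass. The strongest were eIF4EHP, which shares its peak with CG18428, eIF6 (rank 63) and eEF1gamma (rank 111). Splicing and snRNP genes had 10 of 31 (32.3%, exact adjusted p = 0.148) and high mobility group and linker protein genes 2 of 7 (dre4 and HmgZ, adjusted p = 0.632). A list of genes with abundant transcripts outside the ribosome, written before its own peaks were counted, had 16 of 26 (61.5%, exact adjusted p = 1.62e-05). Hsp83, Eno and the ferritin genes Fer1HCH and Fer2LCH, which share a peak, were among its strongest. Counts of optimal summits within gene bodies depend on gene length: kirre had 17 in 394 kb (0.431 per 10 kb) and CG1677 18 in 125 kb (1.44 per 10 kb), against 11 in 15.3 kb for CG14434 (7.20 per 10 kb) and 12 in 27.05 kb for CHES-1-like (4.44 per 10 kb).

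Peaks at 72 of 86 cytosolic ribosomal protein genes were weighed against technical explanations, since a library called an input control could show open, active promoters. The test on oxidative phosphorylation and proteasome genes was chosen after their counts had been seen. A signal at every housekeeping promoter alike is argued against by these genes, of which 23 of 116 had a peak (19.8%, 95% interval 13.004 to 28.3%). Other such lists lay higher, with 37.0% of mitochondrial ribosomal protein, 35.3% of translation factor and 32.3% of splicing genes. A signal at some housekeeping promoters therefore stays open. Peaks of head-to-head neighbours are argued against as the whole source, since 23 of 33 ribosomal protein genes with no such neighbour had a peak (69.7%, 95% interval 51.3 to 84.4%). Of those with a head-to-head neighbour, 49 of 53 (92.5%) had one, so a part played by neighbours stays open. A signal that follows transcript abundance stays open: the abundant genes had a peak in 61.5% of cases (95% interval 40.6 to 79.8%), above all genes but below the ribosomal protein genes (exact p = 0.0269), with overlapping intervals. No biological explanation was tested, because the samples form 1 group.

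The placement of 5 of the 7 strongest peaks within 20 kb at CG14434 on X was seen before it was tested, and the test of chance was chosen after it. Repeated sequence is argued against: of 4194 words of 36 bases in these peaks, 0 (0%) occurred elsewhere in the assembly. Chance placement of strong peaks is argued against by a scan of the whole list, over the 5 to 100 strongest peaks and windows of 5 to 100 kb. The 30 combinations were set after the locus was seen, to replace a first test whose 7 peaks and 20 kb came from the locus. By the smallest p over all combinations, no draw of 10000 was as extreme (permutation p = 1.00e-04, the smallest the draws can give). At single combinations some draws matched the locus, with a permutation p up to 0.0073 for the 100 strongest peaks and 5 kb. The draws reassigned signals among peaks as if neighbouring peaks were independent, which they are not. Extra copies of the locus in the flies and a higher background in its chromatin were not tested, and the biology of the locus was not tested either.

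The tests of the AT-rich words, on reversed words and on GC content, and their bounds were set after the data had been seen. Of the 10 words, several of which overlap, 9 exceeded the same word read backwards at the test summits (exact McNemar test, adjusted p up to 0.0407). TAAATAA did not (11.9% against 12.2%, exact adjusted p = 0.70). Base composition alone gives no such difference within the summits. The comparison has no flank or genome baseline, and a difference present across the whole genome would give it too. Whether base composition alone raised these words over the flanks therefore stays open. Reading a word backwards keeps its bases but not its neighbouring pairs, so a preference for certain base steps stays open as well. A low-GC bias of the libraries also stays open: weaker candidates had a GC content higher at the summit than 500 bp away by 0.301 points, where the optimal peaks were lower (difference -8.11 points), but they are weak calls of the same list, and the drop in the replicates' own calls ranged from -3.57 to -9.54 points.

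A further search asked which words of 8 bases exceeded their reversed form at promoter and at other peaks, after a search over all peaks had shown such words. Of 20 words chosen on 3 arms for exceeding their reversed form, 18 did so on the other arms, and several of the words overlap. Base composition alone gives no such difference. A difference present across the whole genome would also repeat on other arms, so this count cannot tie the words to the summits. At promoters, CAACACTG was at 2.25% of 1466 test summits (reversed form 0%, exact adjusted p = 4.66e-09), and at 0.244% of other test summits. ATCGATAG, which overlaps the DRE, was at 2.93% (reversed form 0.273%, exact adjusted p = 8.65e-09) and AACAGCTG at 2.11% (0.205%, adjusted p = 2.55e-06). At other peaks, GGCAAACA was at 2.31% of 1642 test summits (reversed form 0.183%, exact adjusted p = 1.89e-08) and at 0.341% of promoter summits, and CACTGAGA at 1.89% (0.122%, adjusted p = 6.54e-07). Compared between the classes, 7 of the 10 promoter words and 2 of the 10 others were more frequent in the class they were chosen in (Fisher's exact test, adjusted p under 0.05). The rest did not pass, among them AATATGTA, chosen at promoters (1.91%, other peaks 2.74%), and AAATATTT, chosen at other peaks (4.20%, promoters 4.57%). Weaker candidates also held GGCAAACA at 1.52%, and no test ties any word to CG1233.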
